A study of Macaca fascicularis with 6 samples.

How the data were processed

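The retinal pigment epithelium (RPE) is the pigmented cell layer between the photoreceptors and the choroid of the eye. RNA was sequenced from the RPE of 6 cynomolgus macaques (Macaca fascicularis), 3 with diabetes and 3 controls, with 1 library per animal. Per the labels' protocols, the RPE was taken with an ophthalmic spatula, RNA was extracted with TRIzol, libraries were made with the Illumina TruSeq RNA kit, and all libraries were pooled and sequenced on a HiSeq X10. No sort or other purification of cells is described in the sources used here, and neither are the sex, age, duration of diabetes or batch of the animals.

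The values are raw read counts per gene, as deposited by the authors in 1 table of 29324 Ensembl gene IDs and 6 columns. The submitters' processing notes name CASAVA 1.7, FastQC 0.11.8, STAR 2.7.3a, HTSeq 0.11.2 and DESeq2 1.26.0. The role of each tool, the genome build, the annotation release and the strand setting of the counting are not given in the sources used here. The table ends with 5 rows that name no gene, in the format that HTSeq writes. They hold reads that overlapped no gene (54.9% to 70.3% of all reads in the table) and reads that overlapped more than 1 gene (0.358% to 0.587%), and the other 3 are at 0 in every library. These rows were kept out of library sizes and tests. Without the strand setting, reads of a gene and of an antisense or overlapping gene may have been counted together, and copies of near-identical genes may have lost reads.

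The gene IDs come without symbols. The reference gene table used here lists 40596 genes and pairs none of them with an Ensembl ID, so 0 of the 29324 IDs could be given a name. Therefore 45 gene lists that had been fixed before the data were examined, among them 3 of complement genes and lists of RPE, photoreceptor, glial, vascular, stromal and immune markers, were not tested. The rule for naming genes, fixed at the same time, asked for symbols and for members of those lists. What remained of it was used. Among genes with an adjusted p under 0.05, an average log2 CPM over 0 and CPM ranges that did not overlap between the groups, the 2 IDs with the largest rise and the 2 with the largest fall are given. Gene length and GC content were likewise not analysed here.

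Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (estimateDisp, then glmQLFit with robust = TRUE and legacy = FALSE, and glmQLFTest). The model held the group alone, with TMM scaling of library sizes and the default filterByExpr filter, which asks for a count of about 10 in at least 3 libraries and left 13829 genes. The test is two-sided, p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called. Standard errors of log2 fold changes were derived from the fitted coefficient and its F statistic. Expression levels are given as CPM, the count of a gene relative to the TMM-scaled library size. For genes found in subsets of the libraries, CPM was taken on the unscaled total of reads in genes. Correlations and principal components used log2 CPM with a prior count of 2. Single values per library were compared with exact two-sided permutation tests, which with 3 against 3 animals cannot give a p under 0.1. Binomial intervals are Wilson 95% intervals. They and the counting intervals of ratios cover counting error only, since reads without molecular identifiers are not independent molecules.

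The libraries held 9887980 to 27508692 reads in genes. On counts simulated for the comparison of diabetic with control RPE, from the means, dispersions and library sizes of the 13829 genes, the test recovered 2% of 50 genes changed 2-fold, 6% of 50 changed 4-fold, 44% of 50 changed 8-fold and 66% of 50 changed 16-fold. It made 6 false calls among 13108 unchanged genes. Only 200 genes were changed in the simulation, while 2984 were called in the data. With fewer changed genes the Benjamini-Hochberg adjustment is stricter, so these rates can understate recovery in the data. The simulation was repeated at 4 times the depth with the same dispersions. No pair of libraries of a group was a duplicate. The counts of each pair differed far beyond sampling noise, with a chi-square of at least 64.9 per degree of freedom.

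Replicate numbers 1 to 3 occur in both groups. The labels name nothing that same-numbered animals share, so the numbers were taken as names only. Same-numbered libraries did not deviate from their group means together (r = -0.34, -0.25 and -0.18). Deviations of 3 libraries from their own mean are tied to each other, so these correlations cannot exclude a shared factor. The alternatives fixed before the data were examined were scaling by DESeq2-style size factors or upper quartiles, no filter or a stricter one, DESeq2 1.42.0, limma-voom 3.58.1 with and without sample quality weights, the legacy edgeR fit, a replicate block, other thresholds and leaving out each library. Alternatives chosen after seeing the data were scaling by total reads in genes, the share of reads in no gene as a covariate, removal of the genes found in Control 2 and 3 alone, Control 1 alone against the diabetic libraries, and leaving out Control 1 together with Diabetes 1. Intervals of shares over genes in the closing section come from resampling the genes. Fixed-seed draws without replacement were used to bring libraries to an equal depth. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.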

Results

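Gene expression was measured by RNA sequencing in the RPE of 3 diabetic and 3 control cynomolgus macaques, each animal giving 1 library. The study asked how the RPE transcriptome of a primate model of early diabetic retinopathy differs from that of control animals, with the complement system as its subject. Reads assigned to genes numbered 27508692, 9887980 and 10280866 in Control 1, 2 and 3, and 16148220, 17173063 and 18937224 in Diabetes 1, 2 and 3. At least 1 read was found for 22338 of the 29324 genes, and 13991 genes had a read in every library. The genes are known here by Ensembl ID only, so the level of complement genes and of RPE markers was not analysed here.

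The RPE libraries did not fall cleanly into the 2 groups. Control 2 and Control 3 were alike (Pearson r = 0.95 across 13829 genes, which are not independent replicates), and so were the 3 diabetic libraries (mean r = 0.92, range 0.90 to 0.95). Control 1 resembled the other controls (r = 0.79 and 0.82) no more than it resembled the diabetic libraries (r = 0.82 to 0.83). Control 2 and 3 differed most from the diabetic libraries (mean r = 0.66). The first principal component, with 66.9% of the variance, placed Control 2 and 3 at -139.6 and -151.4, Control 1 at -16.5, Diabetes 1 at 56.7 and Diabetes 2 and 3 at 126.6 and 124.2. The second, with 15.2% of the variance, set Control 1 at 114.0 apart from the other 5 libraries, which lay between -51.9 and -4.75.

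**Figure D1:**
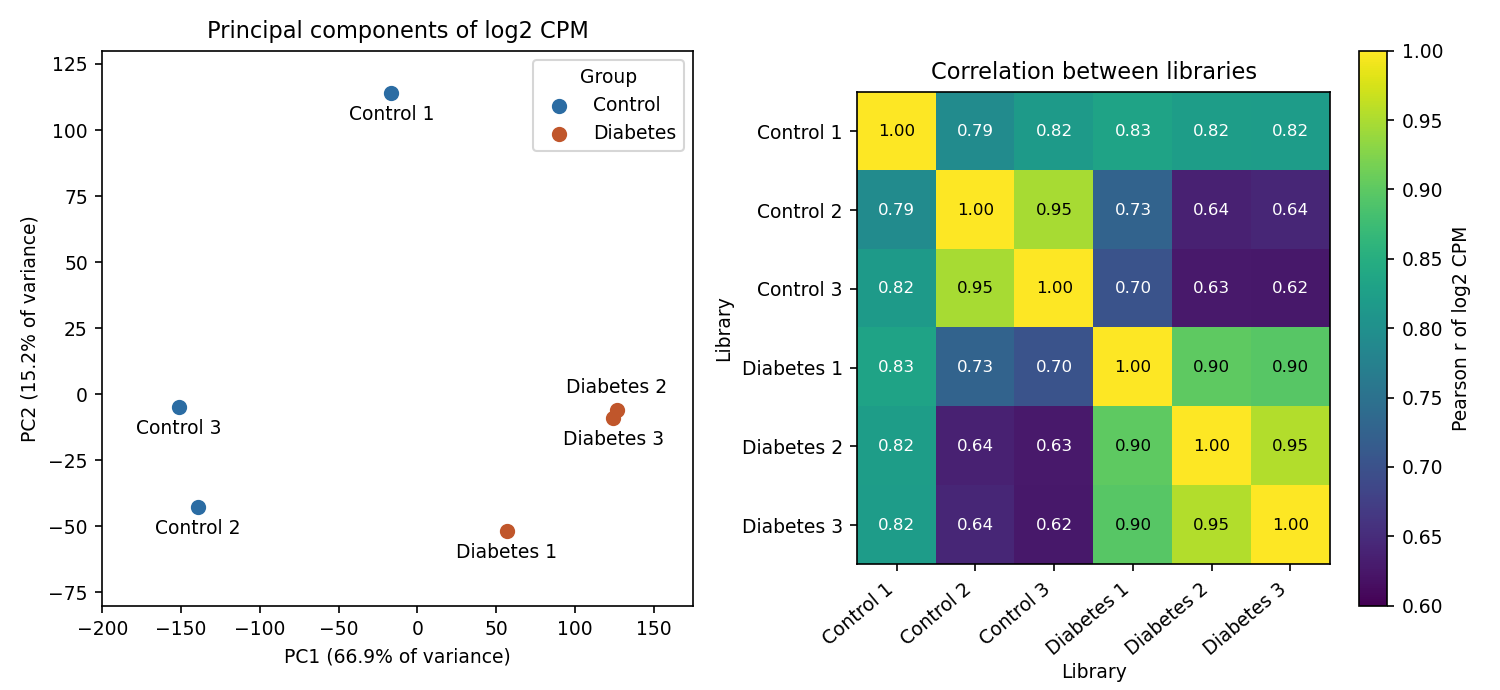
The left panel plots each library on the first 2 principal components of log2 CPM, coloured by group, and the right panel gives Pearson's r between each pair of libraries across 13829 genes. Control 1 lies at -16.5 on the first component, between Control 2 and 3 and the diabetic libraries, and its correlations with the other 5 libraries all lie between 0.79 and 0.83.

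Expression differed widely between diabetic and control RPE. Of 13829 genes tested, 2984 (21.6%) were called, 1343 higher and 1641 lower in diabetes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 and 3). All called genes changed by more than 2-fold. The median size of the change was 2.89 on the log2 scale for genes that rose and 2.72 for genes that fell, and 365 of the rising and 266 of the falling genes changed by more than 16-fold. The biological coefficient of variation was 59.1%. The groups' CPM ranges did not overlap for 2801 of the called genes, and for 42.5% of all tested genes, where chance alone gives 10% on average over splits of the libraries. Genes vary together, so a single split can lie far from that average by chance.

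Rising and falling genes were spread differently over the levels of expression. Among 677 abundant genes (average log2 CPM of 8 and over), 123 were called higher and 21 lower in diabetes. Among 5073 genes from 4 to 8, 641 were higher and 516 lower. Below 4 the balance was the other way, with 568 higher and 1048 lower of 7460 genes from 0 to 4, and 11 higher and 56 lower of 619 genes under 0. The split between directions depended on the scaling, among other choices. TMM factors were 0.98, 1.47 and 1.42 for Control 1, 2 and 3 and 0.98, 0.73 and 0.69 for Diabetes 1, 2 and 3. With library sizes taken as total reads in genes, which moved the median log2 fold change by -0.67, 716 genes were called higher and 2429 lower, or 22.8% higher against 45.0% under TMM. The genes at log2 CPM of 8 and over held more rises than falls under that scaling too (75 against 39), and those from 4 to 8 did not (324 against 807).

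**Figure D2:**
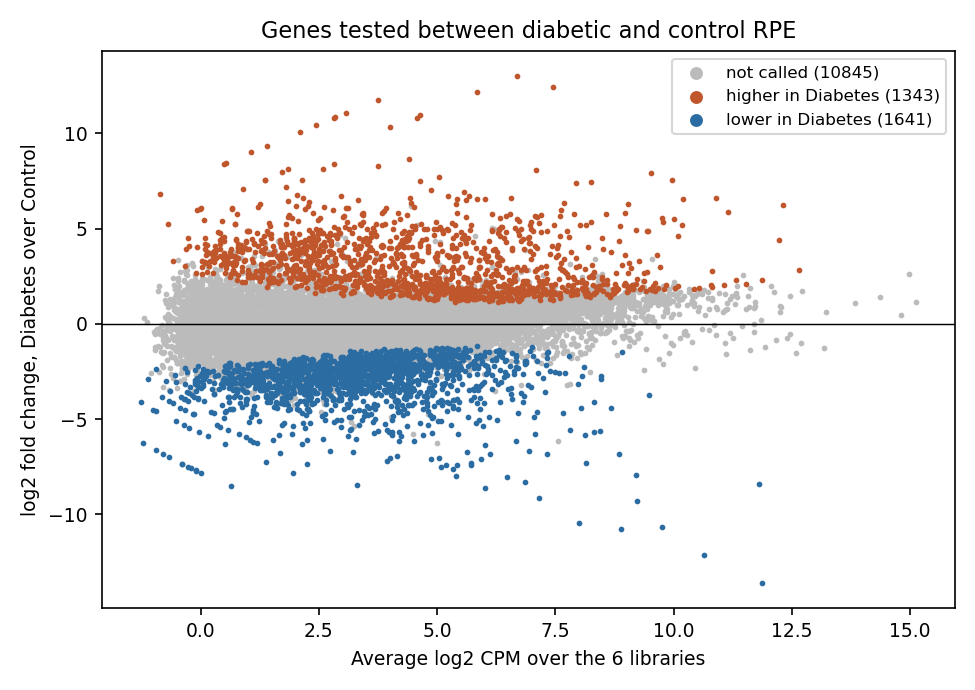
Each point is 1 of the 13829 tested genes, with its average log2 CPM over the 6 libraries on the horizontal axis and its log2 fold change of Diabetes over Control on the vertical axis. Orange points are the 1343 genes called higher in diabetes and blue points the 1641 called lower, and above a log2 CPM of 8 the called genes are mostly higher (123 against 21).

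The genes with the largest changes were near silent in one group. ENSMFAG00000035787 had 1 read in the 3 control libraries together and 80, 6501 and 1219 reads in Diabetes 1, 2 and 3. Its level was 206 ± 275 CPM in diabetes against 0.012 ± 0.021 CPM in controls (mean ± SD, n = 3 each). The ratio of pooled reads was 10470 (95% counting interval 1879 to 413600), with an adjusted p of 0.0055 in edgeR. ENSMFAG00000043130 had 3 reads in the controls and reached 997.2, 32.5 and 25.2 CPM in Diabetes 1, 2 and 3, a pooled ratio of 7384 (2526 to 35810, adjusted p of 0.0040 in edgeR). The size of both changes was uncertain, because levels within the diabetic group differed by 103-fold and 39.5-fold from the lowest to the highest library. With limma-voom neither gene passed (adjusted p of 0.065 and 0.053), nor did they against Control 1 alone, at log2 fold changes of 12.11 and 12.88 (edgeR adjusted p of 0.38 and 0.40). With the share of reads in no gene as a covariate, the fitted log2 fold change of ENSMFAG00000035787 was -4.93 (edgeR adjusted p of 0.69). That of ENSMFAG00000043130 was 36.66 (edgeR adjusted p of 0.027). The share does not overlap between the groups, so both fitted values are extrapolations. Neither measures the difference in level between the groups.

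Of the genes that fell, ENSMFAG00000038867 stood at 1536 and 1305 CPM in Control 2 and 3, at 1.71 CPM in Control 1 and at 0, 0.48 and 1.16 CPM in the diabetic libraries. Its log2 fold change was -10.78 ± 2.29 (SE), with an adjusted p of 0.018 in edgeR. ENSMFAG00000041542 stood at 345 and 501 CPM in Control 2 and 3, at 0.97 CPM in Control 1 and at 0.39 to 0.63 CPM in diabetes (log2 fold change -9.11 ± 1.83, adjusted p of 0.016 in edgeR). For both genes the high levels were those of Control 2 and 3. With limma-voom neither passed (adjusted p of 0.17 and 0.21), and without the low-count filter ENSMFAG00000038867 did not (edgeR adjusted p of 0.054), nor did ENSMFAG00000041542 with a replicate block (0.107). Neither passed when Control 2, Control 3, Diabetes 2 or Diabetes 3 was left out (edgeR adjusted p from 0.053 to 0.098), while the log2 fold changes stayed about as large (-11.9 to -10.3 and -9.00 to -8.42). Against Control 1 alone their log2 fold changes were -1.76 and -1.0 (edgeR adjusted p of 0.44 and 0.64). With the covariate, which extrapolates in the same way, they were 2.77 and 3.00 (edgeR adjusted p of 0.59 and 0.11).

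A set of 244 genes was abundant in Control 2 and Control 3 and nearly absent from the other 4 libraries, Control 1 included. These genes had at least 10 CPM in both libraries and at least 20 times the level of any other library, a criterion set after the data were seen. They took 9.99% of the reads in genes of Control 2 and 7.29% in Control 3, against 0.0256% in Control 1 and 0.0173% to 0.0267% in the diabetic libraries. The same criterion applied to each of the other 61 subsets of the 6 libraries gave at most 9 genes. It gave 6 genes for the 3 diabetic libraries and 0 for the 3 controls. In a count by reads, 174 genes had at least 10 reads in both Control 2 and Control 3 and 0 in the other 4 libraries. By the same count, 18 genes were present in all 3 controls and at 0 in diabetes, and 13 were present in all 3 diabetic libraries and at 0 in controls. Since it asks for reads in at least 3 libraries, the filter on low counts removed 146 of the 244 genes before the test, and 87 of the 98 that were tested are among the 1641 called lower in diabetes.

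**Figure D3:**
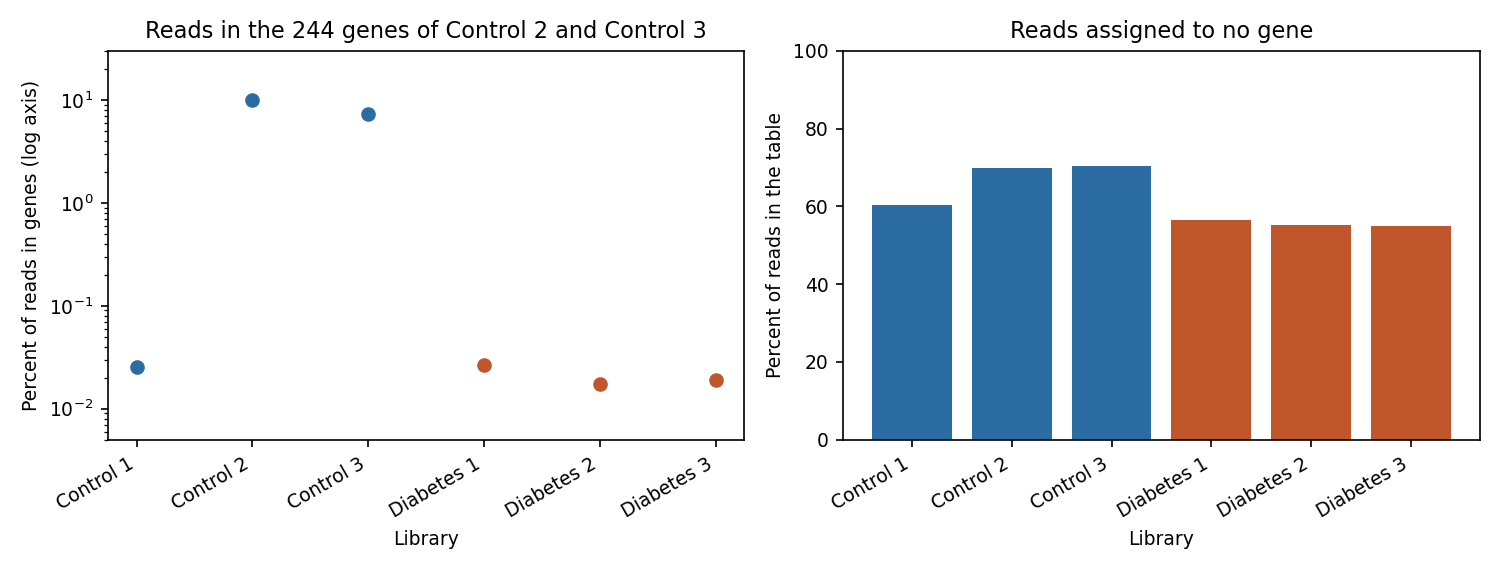
The left panel gives, on a log axis, the percent of each library's reads in genes that fell in the 244 genes, with Wilson 95% intervals that are smaller than the points, and the right panel the percent of all reads in the table that were assigned to no gene. Control 2 and 3 stand at 9.99% and 7.29% on the left and at 69.9% and 70.3% on the right, above the other 4 libraries in both.

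Control 2 and 3 also differed from the rest in how their reads were assigned. The share of reads that overlapped no gene was 60.2%, 69.9% and 70.3% in Control 1, 2 and 3 and 56.6%, 55.3% and 54.9% in Diabetes 1, 2 and 3. The group means were 66.8% ± 5.71 and 55.6% ± 0.877 (SD, n = 3 each, exact permutation test p = 0.1, the smallest possible, and 0.3 after Benjamini-Hochberg adjustment over 6 library measures). At an equal depth of 9887980 reads in genes, 19897 and 18622 genes were detected in Control 2 and 3, against 16245 in Control 1 and 16027 to 16604 in the diabetic libraries. The number detected was not shown to differ between the groups (exact permutation test p = 0.3, n = 3 each).

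The number of called genes depended on single libraries. Without Control 1, 7406 genes were called, 3303 higher and 4103 lower, and these included 2964 of the 2984. Without Control 2, 986 genes were called, 622 higher and 364 lower, and without Control 3, 521 were called, 354 higher and 167 lower, so that rises then outnumbered falls. Rises also outnumbered falls with limma-voom (1053 against 684). Without Diabetes 1, 3141 genes were called, 1118 higher and 2023 lower. Without Diabetes 2 or Diabetes 3, 402 and 346 were called, of which 42 and 18 were lower in diabetes. With Control 1 as the only control and its spread assumed to equal that of the diabetic libraries, 328 genes were called, and 66 of the 2982 original calls tested there had the opposite sign. Of the genes called without Control 1, 6200 were also tested in all 6 libraries. Control 1 took no part in their call, but its reads counted in the filter that kept them. That filter kept 3167 of the 3303 higher and 3033 of the 4103 lower genes. Falling genes near silent in Control 1 were thus more easily left out, which favours places nearer to Control 2 and 3. In the 6200 genes, Control 1 lay within the diabetic range for 1592 (25.7%), at or past the nearer of Control 2 and 3 for 930 (15.0%), and elsewhere for the rest.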

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

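All tests in this part were chosen after the results were seen, except the count of other splits.

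The share of reads that overlapped more than 1 gene, which no comparison of genes uses, stood above its level in the controls. It was 0.512% ± 0.0722 in diabetic and 0.380% ± 0.0300 in control libraries (SD, n = 3 each), higher in each diabetic library than in any control (exact permutation test p = 0.1, the smallest possible, and 0.3 after adjustment). The share is taken over all reads in the table, of which 60.2% to 70.3% in controls and 54.9% to 56.6% in diabetes overlapped no gene. It is therefore not independent of that difference. Control 3 had 0.414% of all reads in more than 1 gene and 70.3% in none, and Diabetes 1 had 0.443% and 56.6%. Taken over only the reads that overlapped a gene, the share was thus higher in Control 3 than in Diabetes 1. On that base the diabetic libraries did not all stand above the controls. The group means on that base were not compared.

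The first pattern is the 2984 genes called between the groups. Splitting the 6 libraries in the other 9 ways into 3 and 3 called 0 genes each with edgeR and 0 with limma-voom (50 to 3039 genes at an unadjusted p under 0.05, against 5667 in the real split), but 1 of 10 splits is the lowest share possible, which is too few for a share under 0.05. Each of the other 9 splits also mixes control and diabetic libraries within a group. That widens the spread within groups, so their 0 calls do not measure how many genes chance would call. The choice of composition scaling is argued against as the whole cause, since 2355 of the calls stayed in the same direction under total-read scaling. That holds mainly for the falls. With 716 genes called higher under that scaling, at most 716 of the 1343 rises can have stayed. For the other rises the choice of scaling stays open. The share of reads assigned to no gene cannot be told apart from diabetes, because it separates the groups completely, and with it as a covariate 36 of the calls remained. Diabetes itself stays open as an untested explanation.

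The second pattern is the place of Control 1 between Control 2 and 3 and the diabetic libraries. Its greater depth does not account for it, since at equal depth its mean correlation with Control 2 and 3 was 0.8076, and at full depth 0.8034 by the same formula. A single mixture of the 2 kinds of RNA is argued against by the 318 and the 23 genes described below. Such a mixture needs a single share of the Control 2 and 3 kind. From pooled reads, 318 genes at least 20-fold higher in Control 2 and 3 than in every diabetic library gave 0.727% (bootstrap 95% interval over genes 0.346 to 1.503). The median over 2861 other genes called lower in diabetes without Control 1 was 16.5% (15.8 to 17.4), 10.95 times the upper bound, and their pooled share was 16.1%. The shares differed, but the 318 and the 2861 genes were not chosen alike. The 2861 genes had passed the filter that counts reads of Control 1, which favours a higher share, and the 318 were not filtered. How much of the gap this makes was not measured. A reverse set, of 23 genes at least 20-fold higher in every diabetic library than in Control 2 and 3, was not filtered either. Control 1 stood below 25% of the diabetic mean for 20 of them, at a median of 6.58%. A share as low as that of the 318 genes would leave it near the full diabetic level. For these genes, which are few in the reverse set, the values argue against a single mixture. A diabetic library carrying a control label cannot be told apart, since the highest correlation of Control 1 with a diabetic library (0.8319) lies below the lowest among those (0.8966), and its highest with a control (0.8185) below that of Control 2 with 3 (0.9478).

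The third pattern is the genes abundant in Control 2 and 3. Loss in diabetes cannot be told apart from other explanations. Of those 318 genes 98.74% lay below 25% of the Control 2 and 3 mean in Control 1, which is not labelled diabetic, but that low level is part of the pattern itself and comes from 1 library. RNA of another tissue in these 2 scraped samples is a possible explanation that also stays open, since 0 of the gene IDs have a symbol by which marker genes could be looked up. Differences between animals were not tested.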

How the results depend on the processing

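The alternatives that use total-read scaling, the unassigned-read covariate, Control 1 alone, the removed gene set, or leave out Control 1 with Diabetes 1 were chosen after seeing the data. The total of 2984 called genes stayed within 1.5 times under 10 of 22 alternatives. Among these 10, the added 2-fold threshold could not change the total, since all called genes changed by more than 2-fold. Leaving out 1 library gave 346 to 7406 called genes, 328 to 3303 higher and 18 to 4103 lower, the highest without Control 1 and the lowest without Diabetes 3. Limma-voom called 1737 genes (1053 higher, 684 lower), and with sample quality weights, which were 0.192 for Control 1 and 0.419 for Diabetes 1, it called 8536 (4114 higher, 4422 lower). DESeq2 called 2484 genes lower, and 4430 in all. An adjusted p under 0.10 gave 5018 (2254 higher, 2764 lower), total-read scaling 716 higher, the unassigned-read share as a covariate 111 (87 higher, 24 lower), Control 1 alone 328 (266 higher, 62 lower), and leaving out Control 1 and Diabetes 1 gave 9297 (4056 higher, 5241 lower). The fit with a replicate block called 493 genes (390 higher, 103 lower). The labels name nothing that same-numbered animals share. The deviations of same-numbered libraries from their group means correlated negatively (-0.34, -0.25 and -0.18), although in raw levels Control 1 and Diabetes 1 were closest to each other across the groups (r = 0.83). The cause of these shifts was not tested. None of the calls changed sign except 357 of 2984 with the covariate and 66 of 2982 with Control 1 alone. Upper-quartile scaling moved the median log2 fold change by -0.15. The 4 named IDs kept direction in 73 of 76 alternative values and lost the call in 18 of these. DESeq2 gave no adjusted p for ENSMFAG00000043130, both falling IDs are in the removed set, and the stricter filter removed ENSMFAG00000041542. With the covariate 3 reversed, to -4.93 for ENSMFAG00000035787, 2.77 for ENSMFAG00000038867 and 3.00 for ENSMFAG00000041542. These values are extrapolations, since the covariate separates the groups completely. Without the low-count filter, the correlations of Control 1 rose to 0.878 with Control 2 and 3 and 0.911 with the diabetic libraries, that of Control 2 and 3 with the diabetic libraries to 0.811, and that within diabetes to 0.95. With 1 CPM required in 3 libraries, Control 1 stood at 0.81 to the diabetic libraries. The planned tests of gene lists and marker lists, with all their alternatives, were not run because the gene IDs carry no symbols. The simulation was drawn 1 time at the real depth and 1 time at 4 times the depth with unchanged dispersions. Of 50 genes changed 2-fold it recovered 2% and 0%, at 4-fold 6% and 10%, at 8-fold 44% and 50%, and at 16-fold 66% and 84%. With 1 draw each, the small differences can be noise of the draw.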

Other observations

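The 6200 genes called without Control 1 had passed the filter that counts its reads. Over them, the median place of Control 1 was 0.45 of the way from the diabetic mean to that of Control 2 and 3 in log2 CPM. A place midway on that scale is already a low percent of the higher level for genes far apart, so the percents below were not set against it. Of 23 genes at least 20-fold higher in every diabetic library than in Control 2 and 3, Control 1 stood below 25% of the diabetic mean for 20, with a median of 6.58% of the diabetic level. Of the 318 genes at least 20-fold higher in Control 2 and 3 than in every diabetic library, it stood below 25% of the Control 2 and 3 mean for 314. Its median there was 0.697% of their level, counting genes with up to 3 reads at that floor, and 127 of the genes were at or under the floor. Both sets were chosen after the data were seen, without using Control 1.

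Small sets of genes were found in single libraries at 20 times the level of every other library. There were 9 such genes in Diabetes 2, 5 in Diabetes 3, 3 each in Control 1, Control 2 and Diabetes 1, and 2 in Control 3. Another 5 genes were shared by Control 1 and the 3 diabetic libraries and low in Control 2 and 3. The 10 most abundant genes took 12.8%, 20.2% and 23.02% of the reads in genes in Diabetes 1, 2 and 3, and 17.0% to 17.7% in the controls.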
